A study of Ovis aries with 3 samples.

How the data were processed

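The study measured RNA in extracellular vesicles, the membrane-bound particles that cells release, from sheep conceptuses (the embryo with its extraembryonic membranes) of day 14 of pregnancy. Per the labels' protocols, each intact conceptus was kept for 24 h in 10 ml of medium that held 10% fetal bovine serum depleted of exosomes. The medium was passed through a 0.2 µm filter and vesicles were precipitated with ExoQuick-TC. Total RNA was purified with the miRNeasy kit, and 5 ng went into SMART-Seq v4 Ultra Low Input libraries, a full-length cDNA method that primes on poly(A) tails. The libraries were sequenced on an Illumina HiSeq as paired-end reads of 50 bp, per the labels' protocols. There were 3 libraries in 1 group and no control group. The labels say that each conceptus was cultured in its own dish but do not tie a library to an animal, so the spread between libraries may be partly technical and the p-values over libraries measure only that spread.

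The authors deposited a single table with 25197 rows, each with an Ensembl identifier, a symbol where the gene has one, a description, 1 value per library and the authors' mean. The genome build was Oar_v3.1, per the submitters' processing notes; the aligner, the counting program and the annotation release are not given in the sources used here. The file does not name the unit. The deposited values were taken as RPKM (reads scaled for gene length and for library depth), rounded by the authors to 1 decimal, because the values of short genes stepped by more than those of long genes and the columns did not sum to a fixed total. FPKM, which counts read pairs, would look alike, and the values are called RPKM-type here. The authors' mean differed from the mean of the 3 columns by at most 0.0667. No library was a copy of another: of the 981 genes at a value of 1 or more in all 3 libraries, 16, 25 and 14 had the same value in libraries 1 and 2, 1 and 3, and 2 and 3.

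Gene lengths were not used here, so whole reads could not be recovered and no count model was fitted. The 1012 rows of the U6 small nuclear RNA family, which have nearly the same length, gave the relative depth. In them 1 read was worth an estimated 0.419, 0.541 and 0.447 in libraries 1, 2 and 3. Only values that rounded to between 1 and a few such steps entered the estimate. Of these, 95.4%, 94.8% and 94.2% lay within 0.1 of a whole multiple of the step fitted to them. Smaller and larger values were left out, and 0.1 is a wide tolerance for steps of this size. By these steps libraries 1 and 3 were 1.29 and 1.21 times as deep as library 2. A value of 1 stood for 2.39, 1.85 and 2.24 reads in a gene as short as U6, and for 23.9, 18.5 and 22.4 reads in a gene 10 times as long. Counting error is therefore large for short genes near a value of 1. The table of sheep RefSeq genes paired 0 of the identifiers with a name, so symbols are those of the deposited table, in which the copies of a name carry a numbered suffix.

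Libraries were numbered in the order of the labels and assigned to columns by their titles. A gene was called detected at a value of 1 or more in all 3 libraries. The share of each library's summed value in its 10 and 100 highest genes was computed. There were 24 gene lists, covering conceptus lineages, other cell types, vesicle markers, cellular machinery and control genes, and these, the tests and most alternatives were fixed before the data were examined. For each list, the members detected were compared with all other rows by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 24 lists; its p is across genes, which are not independent replicates, and describes these libraries. The level of a list was the median log2(value + 1) over its detected members in each library. It was set against 10000 random lists of the same size drawn from the 981 detected genes. A list was called high at or above the 97.5th percentile and low at or below the 2.5th in every library. Lists with fewer than 3 detected members got no call, a minimum chosen after the values were seen. The trophectoderm list was compared with 7 other lists by the difference of medians over all members within each library, with an exact sign-flip permutation test, two-sided, whose smallest possible p with 3 libraries is 0.25. Differences are on the log2(value + 1) scale, which understates those of low genes. Spearman's rho was computed for each pair of libraries across genes, with no p.

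Named genes followed a rule. They were the 25 detected genes with a symbol that had the highest mean, the 3 members with the highest mean of each list, and the 10 detected genes with a symbol and a mean in the upper part (above the median of 4.3) that had the largest SD of log2(value + 1). CD9, CD63, CD81, TSG101, PDCD6IP, HSPA8, PTGS2 and interferon tau were added whatever their value. Genes named beyond this rule are said to be so, and 3 genes that the rule takes are not reported here. Alternatives were other detection thresholds, 2 of 3 libraries, no filter, a pseudocount of 0.1, rescaling by the median ratio, other correlations, and each replicate left out in turn. Both list tests were tested on simulated data. Of 50 simulated lists of 15 genes among the 981, 39 that were raised 4-fold were called high, 46 that were lowered to 0.25-fold were called low and 0 unchanged lists were called. For the detection test, 50 lists of 30 genes in the 25197 rows were simulated at a 4-fold detection rate and 50 at an unchanged rate. An unadjusted p below 0.05 (Fisher's exact test) was reached by 39 and 3 of them. The Benjamini-Hochberg adjustment was not applied to the simulated lists, so these counts describe a looser test than the one used. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.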

Results

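Messenger RNA was profiled in extracellular vesicles shed into culture medium by sheep conceptuses of day 14, the stage of elongation and of interferon tau secretion. Of the study's 3 libraries, all belonged to 1 group, and each gave a value for 25197 annotated genes in RPKM-type units. The question posed by the design was which transcripts the vesicles carried. Summed values were 17480.7, 40060.3 and 9531.8 in libraries 1, 2 and 3, and the highest was 4.20 times the lowest. The depth estimated from U6 copies differed less, since libraries 1 and 3 were 1.29 and 1.21 times as deep as library 2. At a value of 1 or more, 2360, 3428 and 1985 genes were present in the respective libraries.

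Ferritin and ribosomal protein transcripts were the most frequent among the leading genes with a symbol. Among genes with a symbol, FTH1, the heavy chain of the iron store ferritin, had the highest mean, 318 ± 309 (SD, n = 3), with 146.9, 674.3 and 132 in libraries 1, 2 and 3. The light chain copies FTL_4 and FTL_2 followed at 235 ± 214 and 123.5 ± 98.9 (SD, n = 3). GAPDH, a glycolytic enzyme, reached 101.2 ± 71.2 and UBB, a ubiquitin gene, 91.2 ± 107 (SD, n = 3). The row PRO, described only as a protease, averaged 174 ± 134 (SD, n = 3).

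Many of the other leading genes encode proteins of the ribosome. RPS25_1 averaged 111.9 ± 71.9, RPL8 105 ± 88.2, RPS18 97.6 ± 89.4 and RPS20 84.1 ± 73.6 (SD, n = 3). Means between 62.9 and 77.1 were found for RPL23A_1, RPS19, RPLP0_1, RPL17_8, RPL31, RPS3 and RPS25_2. The leading 25 also held the 5S ribosomal RNA copy 5S_rRNA_296 (77.3 ± 35.7), the antioxidant enzyme PRDX5 (66.9 ± 77.4), the epithelial keratin KRT8 (64.2 ± 64.7), the calcium-binding S100A11 (63.3 ± 48.3), the microsomal glutathione transferase MGST1 (62.1 ± 90) and the chaperonin HSP10_1 (61.7 ± 56.2; all SD, n = 3). The SDs were of the size of the means or close to it for most of these genes, and library 2 held the highest value of each of the 25. FTL, RPS25, RPL23A, RPLP0, RPL17, HSP10 and 5S ribosomal RNA have several rows in the table, and the division of reads among such copies is uncertain.

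Higher than any named gene stood 3 rows without a symbol, all described as uncharacterized proteins and named here after their values were seen. ENSOARG00000008767 averaged 408 ± 502 (SD, n = 3). ENSOARG00000001948 and ENSOARG00000019903 had means of 1400 ± 1344 and 1342 ± 1328 (SD, n = 3). In library 3 the last pair stood at 180.2 and 69.9. Together they took 13.8%, 13.9% and 2.62% of the summed value of libraries 1, 2 and 3. Of the 25 highest rows, 15 had no symbol. The 10 highest genes of each library held 18.1% ± 8.54 and the 100 highest 40.2% ± 12.8 of its summed value (SD, n = 3).

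A shared set of 981 genes (3.89% of 25197) was detected in all 3 libraries. It comprised 613 genes with a symbol, 252 rows with only an identifier and 116 small or structured RNAs. A further 1292 genes reached the value of 1 in 2 libraries and 2246 in only 1, and 5446 were listed at 0 in all 3. Without replicate 3 the shared set was 1838 genes.

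**Figure D1:**
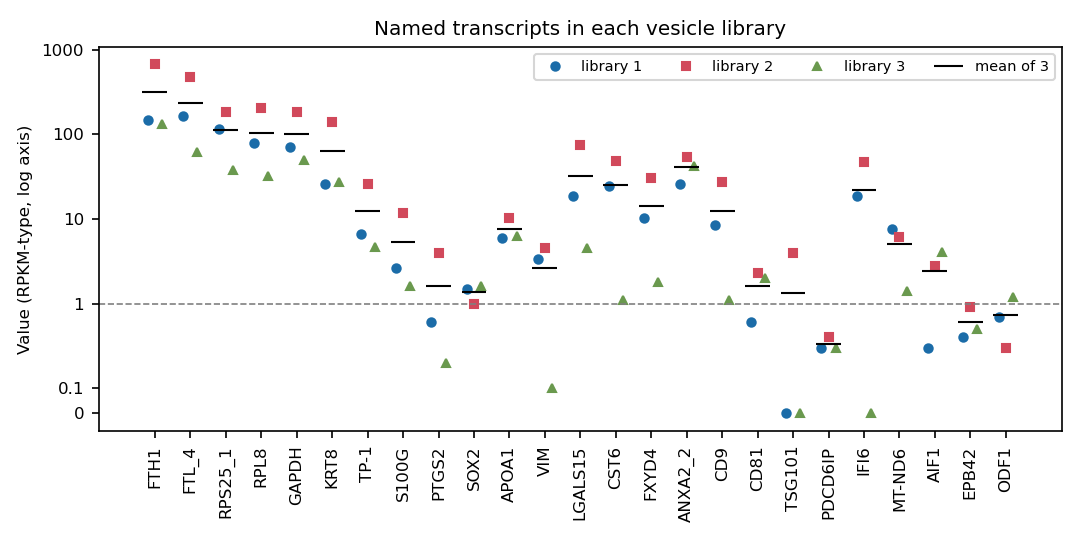
Values of 25 named genes in each vesicle library (points, RPKM-type units, log axis), with the mean of 3 libraries as a bar. Values of 0 were drawn at a fixed low point labelled 0, and the dashed line marks the detection value of 1. FTH1 stood highest at a mean of 318, KRT8 at 64.2 and TP-1 at 12.5, while PDCD6IP and EPB42 stayed below 1 in all 3 libraries.

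Transcripts of the machinery of energy production and protein synthesis were detected far more often than the other rows of the table. No RNA of the conceptus cells was analysed here, and lists were not matched on gene length. The rates of the lists tested here therefore do not separate enrichment in vesicles from general expression or transcript length. Of the 60 nuclear genes for respiratory chain and ATP synthase subunits, 38 were detected (63.3%, against 3.75% of other rows; adjusted exact p = 2.02e-37, Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists). Of 66 ribosomal protein genes 39 were detected (59.1%, adjusted exact p = 5.43e-37). Translation factors were detected in 14 of 31 cases (45.2%, adjusted exact p = 1.44e-11) and proteasome subunits in 16 of 39 (41.0%, adjusted exact p = 3.21e-12). Cytoskeletal genes were detected in 11 of 24 cases (45.8%, adjusted exact p = 2.22e-09) and glycolytic genes in 6 of 17 (35.3%, adjusted exact p = 0.000101). In these lists the ATP synthase subunits ATP5G3, ATP5J and ATP5G2 averaged 51.2 ± 33.9, 35.2 ± 29.0 and 30.8 ± 28.0 (SD, n = 3). The start-codon selection factor EIF1 averaged 57.1 ± 55.3, EIF5A_2 25.6 ± 21.3 and TPT1 21.7 ± 19.5 (SD, n = 3). Actin and its binding partner were represented by PFN1 at 59.2 ± 37.5, by ACTB_1 at 50.2 ± 33.1 and by ACTB_3 at 38.8 ± 19.9 (SD, n = 3). The cytoskeletal list counts 5 rows named ACTB as separate members, and ACTB_1 to ACTB_4 were detected. ACTB_1 is described as actin gamma 1, and the division of reads among these rows is uncertain. The catalytic core subunits PSMA7, PSMA5 and PSMB2 averaged 15.2 ± 13.6, 9.10 ± 5.84 and 9 ± 8.59, and the glycolytic enzymes TPI1 and LDHA 17.2 ± 16.0 and 11.9 ± 9.65 (SD, n = 3).

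Genes encoded by the mitochondrial genome gave a lower detection rate than the nuclear respiratory chain genes, with 2 of 10 detected against 38 of 60 (p = 0.0152, Fisher's exact test; adjusted exact p = 0.0303 over the 4 pairs of lists compared). This pair was chosen after the values were seen. The mitochondrial members with the highest means were MT-ND6 (7.7, 6.2 and 1.4 in libraries 1, 2 and 3), MT-ND5 (4.3, 2.5 and 0.5) and ND2 (1.2, 1 and 1.3), all subunits of respiratory complex I. Against all other rows the mitochondrial list did not pass the test (adjusted exact p = 0.121).

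Cell cycle genes were detected in 5 of 26 cases (19.2%, adjusted exact p = 0.00883). Of the detected members, the highest were the tubulin TUBA1B (26.9 ± 24.8), which the cytoskeletal list also holds, and the histone variant H2AFZ (7.33 ± 6.57; SD, n = 3), which the histone list also holds. The DNA clamp PCNA, not detected because of library 3, stood at 4.7, 26.2 and 0.1. At a detection value of 2 this list no longer passed (adjusted exact p = 0.207). Of 39 histone genes 3 were detected, namely H2AFZ, H2AFV (3.8 ± 3.1) and H3F3A (1.47 ± 0.404; SD, n = 3), and the list did not pass (adjusted exact p = 0.357). The libraries were primed on poly(A) tails, so this rate does not measure histone transcripts without such tails. Zinc finger genes, a large class of nuclear regulators used as a control, were detected less often than other rows, in 2 of 235 cases (0.851%, adjusted exact p = 0.0236). ZNF22 (2.70 ± 0.458; SD, n = 3) was among the detected ones, while ZNF24 (6.4, 7.8 and 0.6) and ZNF75D (2.8, 6.6 and 0.5) fell short in library 3. At a detection value of 2 the zinc finger list did not pass (adjusted exact p = 0.307).

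**Figure D2:**
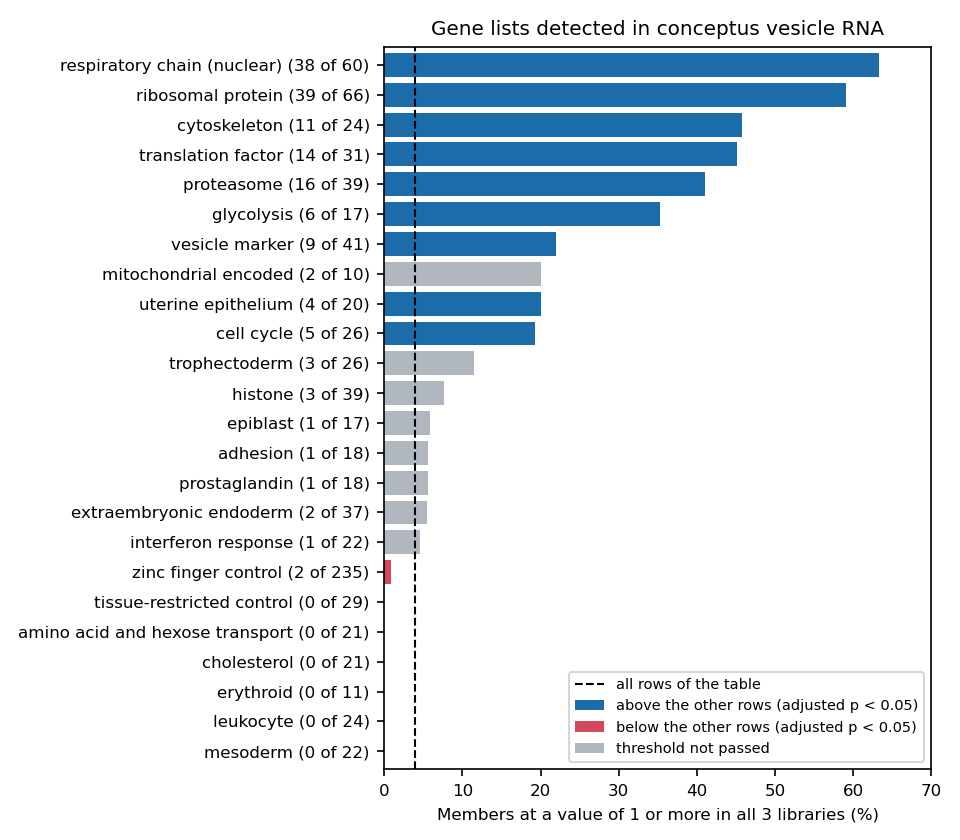
Percentage of each gene list's members at a value of 1 or more in all 3 vesicle libraries (bars), with the rate over all rows, 3.89%, as a dashed line. Nuclear respiratory chain (63.3%) and ribosomal protein genes (59.1%) had the longest bars, and 6 lists had no detected member.

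By level, 2 lists stood out among the detected genes. Ribosomal protein genes had a median log2(value + 1) of 4.83 ± 1.52 (SD, n = 3), at the 100th percentile of random lists in all 3 libraries. Cytoskeletal genes had 3.72 ± 0.89 (SD, n = 3), between the 99.2nd and 99.8th percentiles. The cytoskeletal call was lost without replicate 1, at a level of 3.01, and without replicate 3, at 2.67. Nuclear respiratory chain genes reached 3.05 ± 1.03 (SD, n = 3), at the 99.9th percentile in library 1 and at the 95.3rd in library 3, which missed the call. With replicate 1, 2 or 3 left out, this list was called high, at 3.11, 2.49 and 3.37. Translation factors, at 2.97 ± 1.17, lay at the 97.7th, 97.9th and 53.7th percentiles, and glycolytic genes, at 3.1 ± 1.12, between the 72.3rd and 92.5th (SD, n = 3). Proteasome subunits (2.12 ± 0.64), histones (2.07 ± 0.91) and cell cycle genes (1.67 ± 0.34; SD, n = 3) were called neither high nor low. No list was called low, and 13 lists with fewer than 3 detected members got no call. Ribosomal protein genes made up 9.15%, 8.50% and 4.96% of the summed values of libraries 1, 2 and 3, and 14.3%, 13.3% and 7.25% when rows recognised by description were included.

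**Figure D3:**
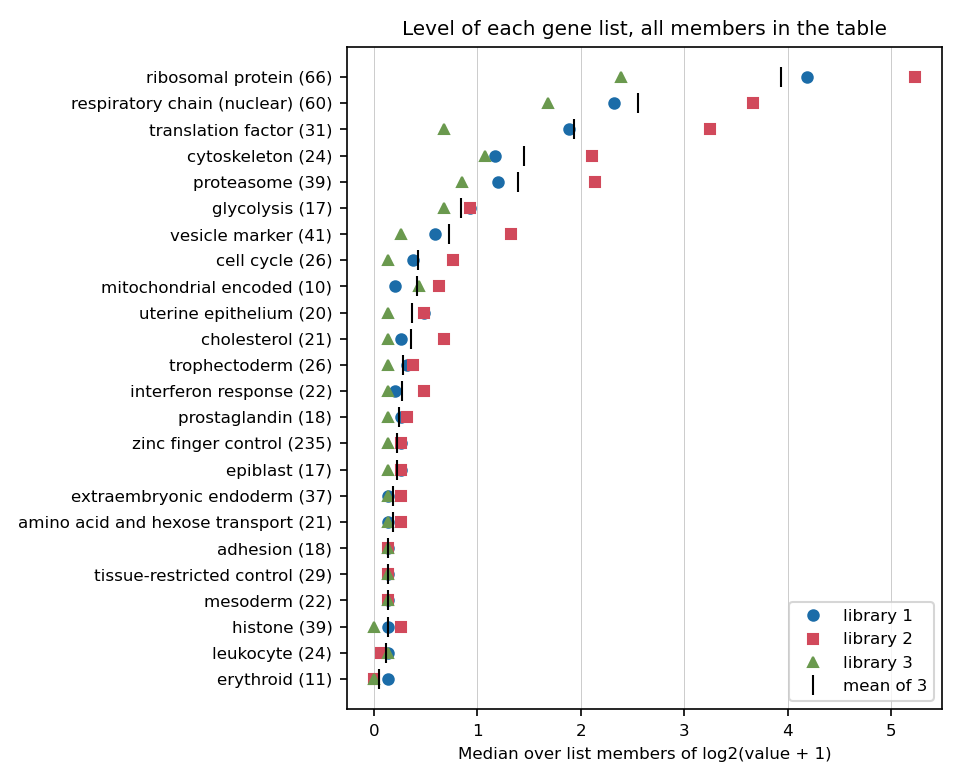
Median log2(value + 1) over all members of each gene list, detected or not, in each library (points) and as the mean of 3 libraries (ticks). Ribosomal protein genes stood highest, and library 2 lay to the right of library 3 for most lists.

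The list of trophectoderm genes, named for the outer epithelium of the conceptus, held a few abundant transcripts. KRT8 averaged 64.2 ± 64.7, the interferon tau gene TP-1, whose product is the signal of pregnancy in ruminants, 12.5 ± 11.9, and the calcium-binding S100G 5.37 ± 5.68 (SD, n = 3). TP-1 stood at 6.7, 26.2 and 4.7 in libraries 1, 2 and 3. Of 52 symbols fixed for this list, aliases included, 26 matched a row and the others were not tested. These 3 were the detected members among the 26, and the list did not pass the detection test (11.5%, adjusted exact p = 0.158). Its level was 3.41 ± 1.20 (SD, n = 3), between the 82.6th and 91.3rd percentiles of random lists. The row ENSOARG00000011496, described as a pregnancy-specific antigen and named here after its values were seen, stood at 16.7, 200.4 and 14.3.

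Lists of other conceptus lineages did not pass the detection test. Among 17 epiblast genes SOX2, a pluripotency regulator, was detected (1.37 ± 0.321, SD, n = 3), while TDGF1 (0.6, 0.8 and 2.4) and DNMT3B (0.3, 2.2 and 0) were not (adjusted exact p = 0.766). SOX2 stood at 1.5, 1 and 1.6 in libraries 1, 2 and 3. The 99th percentile of olfactory receptor genes, a measure of background, was 1.45, 1.025 and 1.75. SOX2 was thus below that percentile in libraries 2 and 3, and background reads are not excluded for it. Of 37 extraembryonic endoderm genes, the apolipoprotein APOA1 (7.53 ± 2.40) and the endocytic adaptor DAB2 (5.73 ± 7.68; SD, n = 3) were detected, and APOA2 stood at 0.9, 5.4 and 2.9 (adjusted exact p = 0.827). DAB2 stood at 1.1, 14.6 and 1.5 in libraries 1, 2 and 3. It was below the olfactory receptor percentile in libraries 1 and 3, where background reads are not excluded for it. No mesoderm gene of 22 was detected (adjusted exact p = 1). Among them, VIM stood at 3.4, 4.5 and 0.1 and DCN at 0.3, 0.8 and 0.2.

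Over all list members, the median of the trophectoderm list differed from those of the 7 other lists by at most 0.23 on the log2 scale as a mean over libraries, and by up to 0.38 within a library. The trophectoderm minus epiblast difference of median log2(value + 1) was 0.06 ± 0.06 (SD, n = 3; p = 0.5, exact sign-flip permutation test). It was 0.10 ± 0.09 against extraembryonic endoderm and 0.14 ± 0.13 against mesoderm (SD, n = 3; exact p = 0.5 for each). Against genes of erythroid cells it was 0.23 ± 0.13, above 0 in 3 of 3 libraries (SD, n = 3; exact p = 0.25, the smallest the design allows). Differences from the leukocyte list, 0.16 ± 0.16, and from the tissue-restricted control list, 0.14 ± 0.13, gave an exact p of 0.5 (SD, n = 3). Among random reassignments of the members to the lists, the differences from the erythroid, leukocyte and tissue-restricted lists lay at the 99.3rd, 99.7th and 98.5th percentiles, a description across genes. Those from the epiblast, extraembryonic endoderm, mesoderm and uterine epithelium lists lay at the 71.7th, 94.6th, 96.3rd and 26.1st. The uterine epithelium list had the only higher median, with a difference of -0.09 ± 0.08 (SD, n = 3; exact p = 0.5). No comparison of this kind could pass 0.05 with 3 libraries. The trophectoderm median over all members was itself only 0.32, 0.38 and 0.14 in libraries 1, 2 and 3. The values were rounded to 1 decimal, so these differences and percentiles compare medians near the floor.

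Genes of the uterine epithelium, the maternal tissue facing the conceptus, were detected in 4 of 20 cases (20%, adjusted exact p = 0.0179). LGALS15, a galectin of the ovine uterine lumen, averaged 32.5 ± 36.8, the protease inhibitor CST6 25 ± 24.0 and the ion transport regulator FXYD4 14.1 ± 14.6 (SD, n = 3). IGFBP1, the remaining detected member, stood at 5.6, 13.3 and 2.2. At a detection value of 2 the list did not pass (adjusted exact p = 0.163). Its level of 3.6 ± 1.88 (SD, n = 3) lay at the 97.3rd, 97.7th and 26.2nd percentiles in libraries 1, 2 and 3, and it was called high without replicate 3, at 3.76. A comparison of the detection rates of the uterine and trophectoderm lists, chosen after the values were seen, did not pass (p = 0.682 before and after adjustment over 4 pairs, Fisher's exact test).

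Among blood cell genes, none of 24 leukocyte genes and none of 11 erythroid genes was detected (adjusted exact p = 1 for each). The lists had been fixed with 26 leukocyte and 21 erythroid symbols, and those that matched no row were not tested. The erythroid result therefore covers only a part of that list. The leading ones were AIF1 (0.3, 2.8 and 4.1), CD74 (1.5, 1.3 and 0.1) and CD68 (0.1, 1.5 and 0) of leukocytes, and EPB42 (0.4, 0.9 and 0.5), HBM (0.3, 0.3 and 0.2) and HEMGN (0.1 in each library) of erythroid cells. Of 29 tissue-restricted control genes 0 were detected (adjusted exact p = 0.827), and the sperm gene ODF1 (0.7, 0.3 and 1.2), the neuronal SNAP25 (0.5, 0.4 and 0.8) and the hormone gene GCG (0.1, 0.2 and 0.7) led them. As a measure of background, the 476 olfactory receptor genes averaged 0.217, 0.171 and 0.183 in libraries 1, 2 and 3. They reached a value of 1 in 15, 6 and 20 cases, and 3 of the 476 did so in all 3 libraries, which met the rule for detection.

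Transcripts of genes whose proteins serve as vesicle markers were detected in 9 of 41 cases (22.0%, adjusted exact p = 9.03e-05). Only RNA was measured, so this does not show the marker proteins. The comparison was with all other rows and not with RNA of the conceptus cells, so it does not show enrichment in vesicles. The membrane-binding annexin ANXA2_2 led with 41.1 ± 14.3, followed by the tetraspanin CD9 at 12.5 ± 13.7, the chaperone HSP90AB1 at 9.83 ± 9.47 and the chaperone HSPA8 at 9.23 ± 9.07 (SD, n = 3). CD9 stood at 8.6, 27.7 and 1.1 in libraries 1, 2 and 3. The tetraspanin CD81 (0.6, 2.3 and 2), the sorting protein TSG101 (0, 4 and 0) and its partner PDCD6IP (0.3, 0.4 and 0.3) were not detected, and no row was named CD63. The level of the list, 2.38 ± 0.86 (SD, n = 3), lay between the 33.3rd and 66.8th percentiles of random lists of detected genes. Over all 41 members and with no filter the median was 0.72 ± 0.54 (SD, n = 3), between the 99.8th and 100th percentiles of random lists of all rows, which is a high call.

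Lists of signalling, synthesis, transport and adhesion genes did not pass the detection test, in which 3.89% of all rows were detected. Of 18 prostaglandin genes the synthase PTGES3 was detected (7.63 ± 4.74; SD, n = 3), and the cyclooxygenase PTGS2 stood at 0.6, 4 and 0.2 and HSD11B1 at 1, 1.3 and 0 (adjusted exact p = 0.766). Of 22 interferon response genes B2M was detected (7.13 ± 6.29; SD, n = 3; adjusted exact p = 0.823), while IFI6 stood at 18.8, 47 and 0 and MX1 at 0.8, 1.6 and 0. Of 18 adhesion genes the galectin LGALS3 was detected (6.07 ± 3.40; SD, n = 3; adjusted exact p = 0.766), with FN1 at 0, 0.1 and 1.7 and ITGB1 at 0.2, 0.9 and 0.6. None of 21 cholesterol synthesis genes was detected, and IDI1 (0.7, 4.5 and 0.6), MSMO1 (0.7, 4.3 and 0.3) and EBP (0.6, 2.1 and 0.5) led that list. None of 21 amino acid and hexose transporters was detected either, with SLC2A1 at 3, 6.7 and 0, SLC7A9 at 1.8, 2.8 and 0.1 and SLC7A1 at 1.5, 0.8 and 1.1 (adjusted exact p = 1 for both lists).

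Ranks of the detected genes were most alike in libraries 1 and 2. Spearman's rho across the 981 genes was 0.747 for libraries 1 and 2, 0.612 for 1 and 3 and 0.514 for 2 and 3; genes are not independent replicates. Library 2 held the highest value for 742 of the 981 genes (75.6%) and library 3 the lowest for 545 (55.6%). The median SD of log2(value + 1) over the libraries was 0.78 (quartiles 0.41 and 1.16), and 0.52 after rescaling by the median ratio. The most variable abundant genes were MGST1, with an SD of 2.64 on the log2 scale and values of 17.3, 165.7 and 3.4, CST6 with 2.41, and the ribosomal protein copy RPL23A_3 with 2.39. SDs between 1.96 and 2.19 were found for the matrix protein gene MGP, PRDX5, BCL2L15, RPS19, MCUR1, RPL7A and EIF1. All 10 had their lowest value in library 3, and 6 of the 10 remained among the most variable after rescaling.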

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

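The added alternatives, all of them for the detection of list members, the leading or variable genes or the ribosomal list by description, were chosen after the data were seen; the others were planned. Of the alternatives for main results, which include the differences between lineage lists, 76 were labelled as kept and 15 as moved. The bounds differed by result and are not listed here. A difference was labelled as kept if its direction did not turn, whatever its size, and none turned. Of the alternatives for single lists and genes, 237 were labelled as kept, 15 newly passed a call, 5 lost one and 1 moved. Genes detected in all 3 libraries numbered 981, but 9771 at any value above 0, 82 at a threshold of 10, 2273 in at least 2 libraries and 1122 to 1838 with a replicate left out (1838 without replicate 3). Lists called high numbered 2, but 7 against genes above 0 in any library, 7 with no filter (vesicle marker, glycolysis, translation factor, respiratory chain and proteasome lists joined) and 2 to 4 with a replicate left out (4 without replicate 3). Lists detected more often than other rows numbered 9, and 7 at a threshold of 2; lists detected less often numbered 1, and 0 at a threshold of 2. Spearman's rho over genes above 0 in any library was 0.499, 0.373 and 0.295 for libraries 1 and 2, 1 and 3, and 2 and 3. Pearson's r of log2 values was 0.870, 0.749 and 0.679, and at a threshold of 10 rho was 0.526 for libraries 1 and 3 and 0.642 for 2 and 3, so that their order turned; the cause was not tested. Ribosomal genes by symbol or description were detected in 58 of 114 cases (50.9%). Of the leading 25 genes, 22 remained when ranked by mean share, and 20 to 24 with a replicate left out. Multiplying by gene length, random lists matched on length and the biological coefficient of variation were not run, because gene lengths were not used here and whole reads were not recovered. No paired analysis was possible because there was 1 group. Depth limits short genes most, since a value of 1 stood for 1.85 to 2.39 reads at the length of U6.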

Other observations

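Of 270 symbol stems with at least 8 members, 8 were detected more often than other rows by Fisher's exact test with Benjamini-Hochberg adjustment over the 270, and 0 less often. The mitochondrial ribosome's small subunit genes (MRPS), which no fixed list holds, were among them, with 9 of 25 detected (36%, adjusted exact p = 1.16e-05), led by MRPS18C, MRPS33 and MRPS16. The large subunit genes of the same ribosome (MRPL) did not pass, with 5 of 41 detected (12.2%, adjusted exact p = 0.393). Complex I subunits of the NDUFB stem had 9 of 10 detected (90%, adjusted exact p = 1.93e-10), and the regulatory proteasome stem PSMD had 5 of 13 (38.5%, adjusted exact p = 0.00362). The other stems that passed were RPL, RPS, ATP, EIF and PSMB, and these, NDUFB and PSMD overlap the fixed lists. Signal recognition particle RNA, which guides ribosomes to the endoplasmic reticulum, was detected in 7 of 19 rows, with mean values of 1.81, 2.15 and 3.06 in libraries 1, 2 and 3. Vault RNA was detected in 0 of 12 rows, 7SK RNA in 2 of 97 and U6 in 47 of 1012, against 3.89% of all rows. The libraries were primed on poly(A) tails, so the rates of these families do not measure RNAs without such tails. These families were looked at after the data were seen.

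Of the tests below, the one on olfactory receptor genes in libraries 2 and 3 was set before its result was seen; those on U6 steps, dilution, background in uterine genes and uterine carry-over were set after. The rule that reads the dilution test was also changed after its value was seen: it first compared the ratio itself with 1.5, which would have excluded dilution, and now requires the lower bound of its bootstrap interval to exceed 1.5. No biological explanation was tested, since the design has 1 group.

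The summed value of library 2 was 4.20 times that of library 3. Values left unscaled for depth would need 1 read to be worth the same in both, but 1 read in a U6 copy was worth 1.21 times as much in library 2, which argues against that. A larger share of background reads in library 3 may contribute, but the ratio of mean olfactory receptor values, library 2 to library 3, was 0.935 with a 95% bootstrap interval of 0.817 to 1.08, so it stays open. A common dilution of all transcripts may also contribute: over 234 genes with a mean of 10 or more the log2 ratios of libraries 2 and 3 spread 1.71 times as widely as those of libraries 2 and 1. After removal of a counting bound that ratio was 1.58 (95% bootstrap interval 1.27 to 1.97), an interval that lies above 1. By the first rule this disfavours dilution, and by the changed rule it leaves dilution open. A single factor would also keep gene lists in proportion. From library 2 to library 3 the ribosomal protein share of the summed value fell from 8.50% to 4.96%. The cytoskeletal share rose from 1.06% to 1.62%. These values argue against a single dilution factor as the whole cause for these genes, while a partial contribution stays open.

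LGALS15 and 3 other listed uterine epithelial genes were detected in all 3 libraries. Background reads as large as in nearly all olfactory receptor genes do not account for LGALS15. In every library LGALS15 was at least 2.57 times the 99th percentile of those genes. For CST6, FXYD4 and IGFBP1 a background source stays open in library 3. There CST6 was 0.629, FXYD4 1.03 and IGFBP1 1.26 times that percentile, while in libraries 1 and 2 all 3 were at least 3.86 times it. Uterine RNA carried over with the conceptus may be a source. Of the 16 other list members, 8 (50%) were above 0 in all 3 libraries, against 12 of 29 (41.4%) tissue-restricted control genes; that they stayed under the detection value says nothing, since the 16 are by construction the undetected members, and 2 of the 20 members are also in other lists. Carry-over and expression by the conceptus cannot be told apart, because RNA of neither tissue was analysed here.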
